A study of Mus musculus with 11 samples.

How the data were processed

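Chromatin immunoprecipitation and sequencing (ChIP-seq) was used on villus epithelium of the mouse jejunum. The transcription factors CDX2 and HNF4A and the histone mark H3K4me2 (dimethylation of histone H3 at lysine 4, found at active promoters and enhancers) were measured. Per the labels' protocols, epithelium was released with 15 mM EDTA and villi were retained on a 70 µm filter, which let crypts through. Villi were fixed with formaldehyde for factor ChIP. Unfixed villi treated with micrococcal nuclease, which cuts DNA between nucleosomes, are also described there, without saying for which libraries. Each library was made from pooled ChIP DNA totalling 10 to 20 ng. All mice with a strain label were on a mixed 129xC57BL6 background.

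Of 11 samples, 10 had a list used here: 5 of factor peaks and 5 of H3K4me2 nucleosomes. The input DNA sample was not analysed here. Groups were taken from the titles. CDX2 in wild type had 2 libraries, and every other group had 1. The labels of both double-knockout H3K4me2 libraries contradict themselves. For the library titled Cdx2-Cdx1, the source and description name Hnf4a as the other deleted gene, and for the library titled Cdx2-Hnf4a the description names Cdx1. All of these labels have Cdx2 deleted. Both libraries are therefore named by title, and nothing is drawn from which other gene they lack. No label says whether the CDX2 wild-type libraries came from separate animals.

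The factor lists give a position and a score per peak, as deposited by the authors. The peak names in the files carry the word MACS, a peak caller, and no score is below 50. What the score stands for, the aligner, the version and the control are not given in the sources used here. The H3K4me2 lists give the position of each called nucleosome and, per the file headers, 10 times the −log10 of a p-value, with a ceiling of 3250. That value is called the nucleosome score here. Its lowest value was between 50.1 and 51.3 in 4 lists and 1.7 in the Hnf4a knockout list, so the deposited lists did not share a threshold. Coordinates are of build mm9, per the submitters' processing notes, and are printed counting from 1. Each library has its own list, and reads per library are not given in the sources used here, so depth is unknown. Peak scores and list lengths move with depth.

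A wild-type peak was called kept where a knockout peak of the same factor overlapped it by 1 bp or more, and lost otherwise. Lost thus means not called, which is not the same as absent binding. Wild-type CDX2 sites were merged regions made of overlapping peaks of both wild-type libraries. Chance overlap came from 1000 circular shifts of a list within chromosomes. Shares have exact Clopper-Pearson 95% intervals, and differences of shares have Newcombe intervals. H3K4me2 was measured as the number of called nucleosomes centred within 1 kb of a site centre. Ratios of these numbers were scaled by the total length of each list, with exact binomial intervals. All intervals cover counting error only. Each knockout had 1 library, so its own spread is unknown and no p-value between conditions was computed.

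For the kept shares, the value was placed among 10000 random sets of peaks of the same size. These were drawn within 10 bins of peak score from all peaks, the tested ones included. For H3K4me2, 10000 control sets with the same wild-type nucleosome counts were drawn, counts of 10 or more being pooled. Controls for CDX2 sites were HNF4A peaks without a CDX2 site, and controls for HNF4A peaks were CDX2 sites without HNF4A. HNF4A peaks written as without CDX2 or HNF4A only lack such a site, but some hold a CDX2 peak of 1 library. Of these 21616 peaks, 18676 had no CDX2 peak in either library. H3K4me2 was not compared with the latter alone. The control pool was resampled for each set, because 900 CDX2 sites without HNF4A are few beside 22376 HNF4A peaks. The central 95% of the random sets is given as their band. Percentiles describe these libraries and not the conditions.

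The procedures were tested on simulated data. For HNF4A kept by CDX2 occupancy over 22376 peaks, 6 of 100 simulations with no effect lay outside the band. When the kept chance of co-occupied peaks was multiplied by 0.7, 100 of 100 did. For H3K4me2 at 1584 CDX2 sites, the simulated knockout was the wild-type list with nucleosomes dropped at random at the same rate everywhere. With no effect, 5 of 50 simulations lay outside, so that band may be somewhat narrow. With nucleosomes near the sites thinned to a further 0.7, 50 of 50 did, with a mean ratio of 0.7002. A thinned list holds no noise between separately called libraries, so how often those would lie outside is unknown.

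Sites were named by a rule set before the data were examined: the 5 highest-scoring kept, lost and knockout-only peaks of each factor comparison, and the 5 co-occupied sites with the largest fall and rise of H3K4me2 in Cdx2 knockout. The last were taken from sites at or above the median wild-type count, with ties, which the rule left open, ordered by the change in the scaled sum of nucleosome scores. Planned parts of that rule that need gene positions, together with tests of gene lists, cell type markers and sequence motifs, were not run, since no genome or annotation of build mm9 was used here. Sites are named by position only. For the same reason the deleted genes themselves were not looked at in each library. A table of gene names for another build gave only the chromosomes of Cdx2 (5), Hnf4a (2) and Cdx1 (18).

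Alternatives covered the overlap rule, stricter or equal-length lists, the window, the scaling, the number of score bins and leaving out each CDX2 wild-type library. A minimum nucleosome score of 52 in every list, summed nucleosome scores, and a comparison with HNF4A peaks lacking CDX2 in either library were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 drew the figures.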

Results

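CDX2, a homeodomain transcription factor of the intestinal epithelium, was mapped in wild-type villi (2 libraries) and in villi lacking Hnf4a (1 library). HNF4A, a nuclear receptor active in enterocytes, was mapped in wild type and in Cdx2 knockout. H3K4me2 was mapped at the level of nucleosomes in wild type, in both single knockouts and in the 2 double knockouts. The CDX2 lists held 12121 and 7441 peaks in wild-type libraries 1 and 2 and 5768 peaks in Hnf4a knockout. The HNF4A lists held 22376 peaks in wild type and 9676 in Cdx2 knockout. The H3K4me2 lists held 250986 nucleosomes in wild type (25.1 Mb covered, median score 230.7) and 262148 in Cdx2 knockout (26.7 Mb, 245.7). The library titled Cdx2-Cdx1 had 292966 (29.2 Mb, 185.6) and the library titled Cdx2-Hnf4a 279224 (28.5 Mb, 232.1). The Hnf4a knockout list was longer, with 485509 nucleosomes over 47.2 Mb and a median score of 55. It reached down to lower scores than the others, and at a score of 52 or more it held 250282.

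The wild-type CDX2 libraries set the level of agreement that lists of one condition reached. Of the peaks of library 2, 21.4% (95% interval 20.5 to 22.4) overlapped a peak of library 1. In the other direction the share was 13.1% (12.5 to 13.7). Shifted lists overlapped at 0.442% and 0.272% on average. Peaks of library 1 were wider, with a median of 570 bp against 255 bp. Among the 3000 highest-scoring peaks of each list, 24.7% (23.1 to 26.3) of library 1 peaks were shared with library 2. The peaks of both lists formed 1584 wild-type CDX2 sites.

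**Figure D1:**
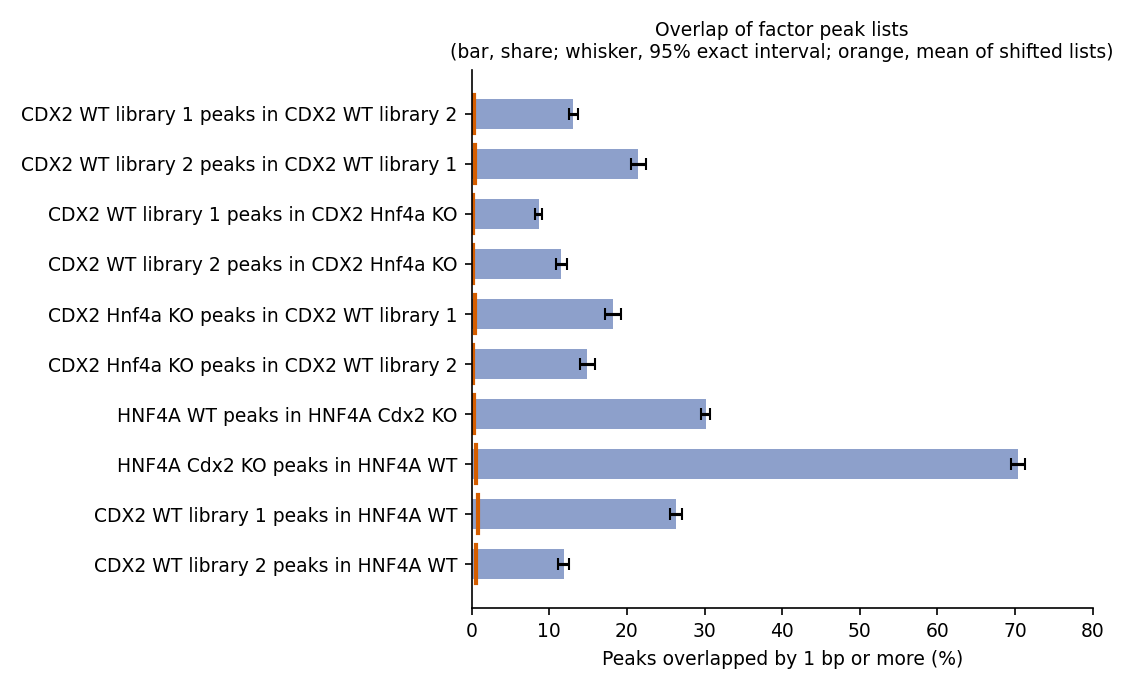
Share of the peaks of one list overlapped by 1 bp or more by a peak of another, in percent, with exact 95% intervals as whiskers and the mean of 1000 shifted lists as orange marks. HNF4A peaks of Cdx2 knockout lay in the wild-type list in 70.4% of cases, while no pairing of CDX2 lists exceeded 21.4%.

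To ask whether CDX2 binding needs HNF4A, CDX2 sites were followed in Hnf4a knockout. CDX2 was called again at 621 of the 1584 sites, or 39.2% (36.8 to 41.7). The site with the highest wild-type score, on chromosome 12 at 16758955 to 16759834, was kept (mean wild-type score 681.6, knockout score 318.1). So was a site on chromosome 9 at 121456252 to 121457194, with 625.9 in wild type and 536.7 in knockout. The highest-scoring lost site lay on chromosome 5 at 29538320 to 29539340 (377.7), followed by one on chromosome 9 at 21229004 to 21229607 (375.9). Every one of the 5 highest kept sites scored above the highest lost site. Peaks called in Hnf4a knockout alone were weak: the highest, on chromosome 17 at 86795146 to 86795451, scored 149.4 and had no H3K4me2 nucleosome within 1 kb in any of the 5 lists. They made up 77.6% (76.5 to 78.7) of the knockout list, with a median score of 56.1 against 66.5 for the rest. By single library, 18.2% of knockout peaks overlapped library 1 and 14.9% overlapped library 2. Between the wild-type libraries, 21.4% of library 2 and 13.1% of library 1 peaks overlapped, so most peaks were unshared there too. Median scores of the whole lists were 57.7 in the knockout, 70.4 in library 1 and 58.0 in library 2.

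The kept share depended on the site definition, being 11.6% of library 2 peaks without library 1 and 8.60% of library 1 peaks without library 2. Among the 3000 highest-scoring peaks, the overlap with the knockout was 18.8% (17.4 to 20.3) for library 1 and 17.7% (16.4 to 19.1) for library 2, against the 24.7% between wild-type libraries. Relative to shifted lists the direction was mixed. Library 2 peaks overlapped the knockout 87.9-fold and library 1 48.5-fold over them. Library 1 peaks overlapped the knockout 41.0-fold and library 2 48.0-fold. Median peak widths were 570 bp in library 1, 255 bp in library 2 and 248 bp in the knockout. The knockout had no replicate, so the lower overlap among the highest-scoring peaks has no replicate check.

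The reverse question was whether HNF4A binding needs CDX2. In Cdx2 knockout, HNF4A was called at 6740 of 22376 wild-type peaks, or 30.1% (29.5 to 30.7). The strongest peaks were kept, led by one on chromosome 16 at 76453883 to 76454588 with scores of 3100 in wild type and 2367 in knockout. Next were peaks on chromosome 6 at 83371728 to 83372778 (2764 and 1772) and chromosome 3 at 87312066 to 87313498 (2726 and 1341). The highest-scoring lost peak, on chromosome 6 at 114346413 to 114347052 (1101), had 7 H3K4me2 nucleosomes within 1 kb in wild type and 2 in Cdx2 knockout. A lost peak on chromosome 11 at 116839585 to 116840084 (863.7) had 2 and 0. A lost peak on chromosome 9 at 106341282 to 106341653 (809.3) had 5 in both. Lost peaks on chromosome 17 at 86832141 to 86832758 (928.1) and chromosome 4 at 115495868 to 115496535 (814.3) had 1 and 1, and 7 and 6. Of these 5 highest-scoring lost peaks, only the one on chromosome 9 overlapped a wild-type CDX2 peak, and only in library 1.

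Of the HNF4A peaks in Cdx2 knockout, 29.6% (28.7 to 30.5) were not in the wild-type list. The highest-scoring lay on chromosome 15 at 77212898 to 77213515 (250.0) and at 78233698 to 78234101 (241.4). Around the latter, 4 nucleosomes were called in wild type and 8 in Cdx2 knockout. The knockout list was shorter, and with lists of equal length the kept share was 53.7%. Each HNF4A group had 1 library here, so the share expected between HNF4A lists of one condition is unknown.

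CDX2 and HNF4A shared many sites in wild type. HNF4A was called at 684 of the 1584 CDX2 sites, or 43.2% (40.7 to 45.7), against a mean of 0.925% in shifted lists. Shifts can place peaks anywhere on a chromosome, so they are a low standard for lists from the same tissue. These co-occupied sites scored higher for CDX2 than the other 900, with medians of 110.0 and 90.6. From the side of HNF4A, 760 of 22376 peaks, or 3.40% (3.16 to 3.64), lay at a CDX2 site. With a CDX2 peak in either library sufficing, that share was 16.5% (16.1 to 17.0). The share depended on the definition of a CDX2 site, since HNF4A lay at 26.4% of CDX2 peaks of library 1 alone and 11.8% of those of library 2 alone. Among the 3000 highest-scoring peaks of each list, 11.8% (10.6 to 13.0) of library 1 and 6.37% (5.52 to 7.30) of library 2 peaks overlapped HNF4A.

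HNF4A peaks at CDX2 sites were kept less often in Cdx2 knockout than other HNF4A peaks of like strength. Their kept share was 33.3% (29.9 to 36.8), or 253 of 760. Score-matched random sets averaged 44.1%, with a band of 41.2 to 46.8, and none of the 10000 sets was as low. The gap was −10.8 points, and −6.02 points without CDX2 library 2 (35.7% against 41.7%). In 8 of 10 score bins the share was lower with CDX2 than without. The gap was widest in the 8th bin, where 19.4% (11.9 to 28.9) of 93 peaks with CDX2 were kept against 46.6% (44.5 to 48.8) of 2145 peaks without. In bins 1 and 3 the share was higher with CDX2, at 13.0% against 7.13% and 9.76% against 9.06%. Before matching, the kept shares were 33.3% with and 30.0% without CDX2, a difference of 3.28 points (−0.0371 to 6.76). Peaks with CDX2 had higher scores, with medians of 129.8 and 80.4. The unmatched difference was −6.91 points (−12.0 to −1.81) with lists of equal length.

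**Figure D2:**
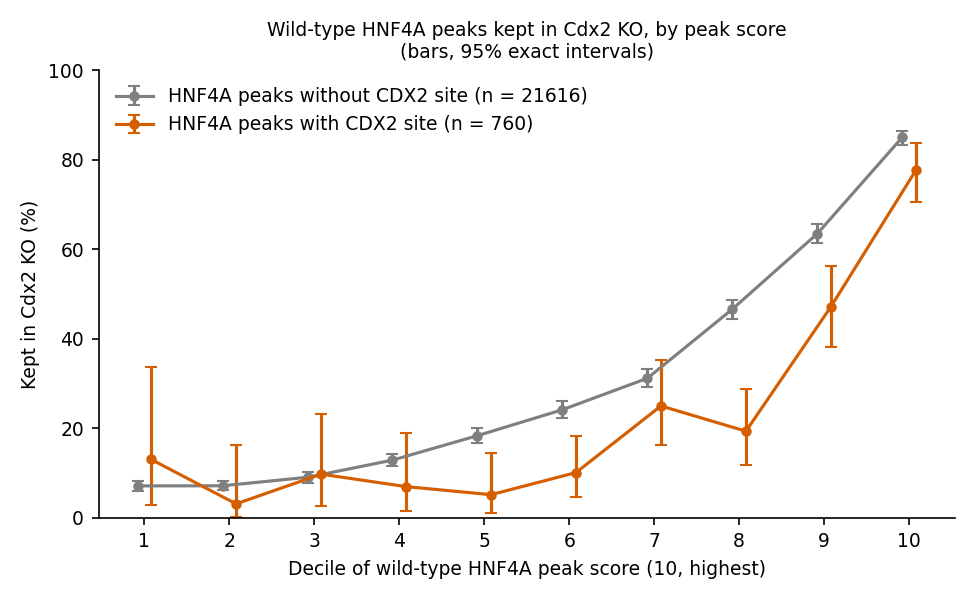
Share of wild-type HNF4A peaks called again in Cdx2 knockout (percent, vertical axis) in 10 bins of wild-type peak score (horizontal axis), for 760 peaks with a CDX2 site and 21616 without; bars are exact 95% intervals. In the highest bin the shares were 77.6% with CDX2 and 85.0% without.

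The reciprocal comparison gave no stable difference. CDX2 was kept in Hnf4a knockout at 41.5% (37.8 to 45.3) of 684 sites with HNF4A and at 37.4% (34.3 to 40.7) of 900 sites without. Score-matched sets averaged 43.7% (41.2 to 46.1), and the observed share was at their percentile 3.94. The sets were drawn from all CDX2 sites, the 684 included, which tends to pull their mean towards the observed share. Using the peaks of a single wild-type library turned the direction. With library 2 alone, 32.1% were kept with HNF4A against a matched 22.7%. With library 1 alone, the shares were 12.9% and 11.7%. The shares with HNF4A lay above their bands, at percentile 100 for library 2 and 99.8 for library 1. With lists of equal length, 51.9% were kept with HNF4A against a matched 50.3%, at percentile 74.7.

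At CDX2 sites, fewer H3K4me2 nucleosomes were called in Cdx2 knockout. The mean within 1 kb was 2.82 per site in wild type and 2.19 in the knockout, a scaled ratio of 0.746 (0.713 to 0.780). HNF4A peaks without a CDX2 site and with the same wild-type counts gave 0.873 (band 0.852 to 0.893), and none of the 10000 sets was as low. Of the 1199 CDX2 sites with a nucleosome in wild type, 254, or 21.2%, had none in the knockout. The ratio was 0.775 (0.732 to 0.820) at the 684 co-occupied sites and 0.701 (0.653 to 0.754) at the 900 CDX2 sites without HNF4A. At HNF4A peaks without CDX2 it was 0.874 (0.865 to 0.884).

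Single sites were taken from the 372 co-occupied sites at or above the median wild-type count of 4. The largest falls in Cdx2 knockout were on chromosome 1 at 52312988 to 52313473 and on chromosome 5 at 53434497 to 53435756, each from 7 nucleosomes to 1. Counts there were 7 and 8 in Hnf4a knockout, or 5 and 7 at a score of 52 or more, 3 and 2 in the library titled Cdx2-Cdx1 and 0 and 0 in the library titled Cdx2-Hnf4a. The other 3 of the 5 largest falls, on chromosome 19 at 11144571 to 11145514 and on chromosome 17 at 86684087 to 86684986 and 24111861 to 24112621, had 2, 2 and 3 in the former double knockout and 0 in the latter. The largest rises, on chromosome 12 at 102033593 to 102034188, chromosome 19 at 9057112 to 9057964 and chromosome 16 at 46848132 to 46848745, went from 4 to 7. At 4 of the 5 largest rises the scaled sum of nucleosome scores was lower in the knockout.

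**Figure D3:**
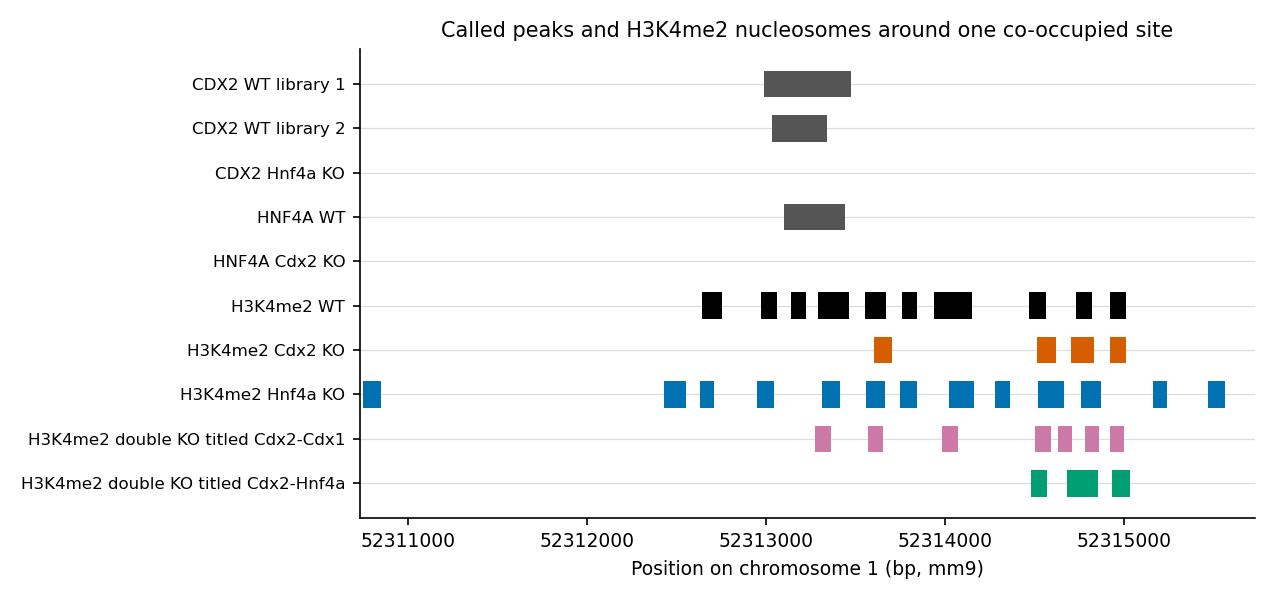
Map of 5 kb of chromosome 1 (mm9, horizontal axis in bp) around the co-occupied site at 52312988 to 52313473, with 1 row per library and a box for each called peak or H3K4me2 nucleosome. Within 1 kb of the site centre, 7 nucleosomes were called in wild type, 1 in Cdx2 knockout and 7 in Hnf4a knockout, whose list has a looser threshold and holds 5 there at a score of 52 or more.

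At HNF4A peaks, H3K4me2 in Hnf4a knockout lay within the band of control sites. The scaled ratio to wild type was 0.748 (0.741 to 0.755) with the lists as deposited, and CDX2 sites without HNF4A with the same counts gave 0.753 (band 0.735 to 0.771). The low ratio went with the looser threshold of the Hnf4a knockout list: at a score of 52 or more in every list, a setting added after seeing the data, it was 1.00 (0.991 to 1.01). At co-occupied sites the Hnf4a knockout ratio was above that of count-matched HNF4A peaks without CDX2 with either list. It was 0.763 against 0.715 (band 0.6998 to 0.729) as deposited, and 1.07 (1.02 to 1.13) against 0.990 (0.967 to 1.01) at a score of 52 or more.

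**Figure D4:**
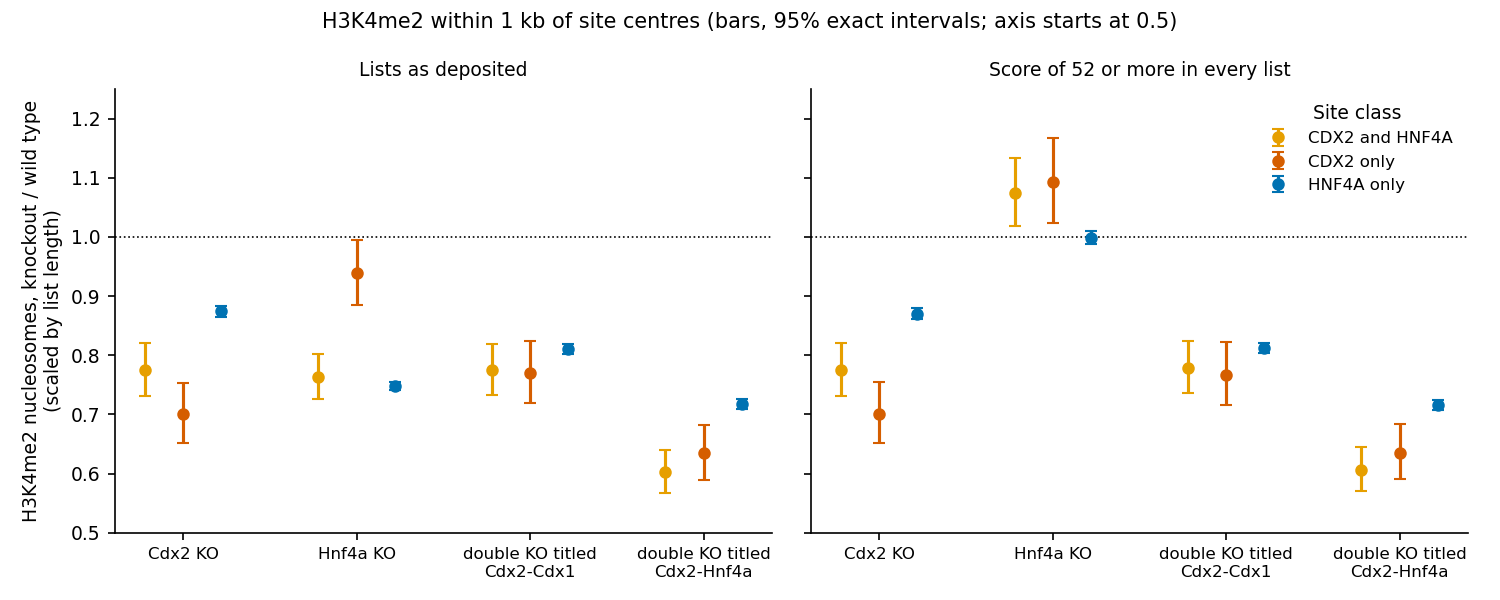
Ratio of called H3K4me2 nucleosomes in each knockout to wild type (vertical axis, scaled by list length) within 1 kb of sites with CDX2 and HNF4A, CDX2 only or HNF4A only, with the lists as deposited and at a score of 52 or more; bars are exact 95% intervals. The Hnf4a knockout ratio at HNF4A only sites moved from 0.748 to 0.999 between the panels, while the Cdx2 knockout ratios at CDX2 only sites were 0.701 in both.

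The double knockouts were set beside the single knockouts at the 684 co-occupied sites. The library titled Cdx2-Cdx1 had a ratio to wild type of 0.775 (0.733 to 0.818), and relative to Cdx2 knockout its ratio was 1.00 (0.943 to 1.06). Count-matched HNF4A peaks without CDX2 gave 0.798 (band 0.774 to 0.824) in this library, and the co-occupied sites lay inside that band at percentile 2.69. Some label of each double knockout names Hnf4a as the other deleted gene, so controls at HNF4A peaks may not be neutral there. A place inside their band thus does not show that co-occupied sites were spared. In Cdx2 knockout the same controls gave 0.863 (0.837 to 0.888), above the 0.775 at co-occupied sites. Controls need not be neutral in Cdx2 knockout either. The ratio was 0.843 (0.831 to 0.855) at the 15129 HNF4A peaks without CDX2 that were lost there. At the 6487 kept ones it was 0.919 (0.904 to 0.935). The library titled Cdx2-Hnf4a had 0.603 (0.568 to 0.640) relative to wild type and 0.778 (0.731 to 0.829) relative to Cdx2 knockout, with controls at 0.704 (0.673 to 0.735). At the 900 CDX2 sites without HNF4A, both lay below their controls, at 0.770 against 0.859 (0.824 to 0.894) for the library titled Cdx2-Cdx1 and 0.634 against 0.724 (0.683 to 0.764) for the other. Of the 653 co-occupied sites marked in wild type, 14.5% had no nucleosome in Cdx2 knockout, 9.49% had none in the library titled Cdx2-Cdx1 and 26.6% had none in the library titled Cdx2-Hnf4a. The lower level of the last library extended to HNF4A peaks without CDX2, where its ratio was 0.717 (0.709 to 0.726) against 0.811 (0.802 to 0.820) in the library titled Cdx2-Cdx1. The labels contradict each other on the other gene deleted in each library.

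**Figure D5:**
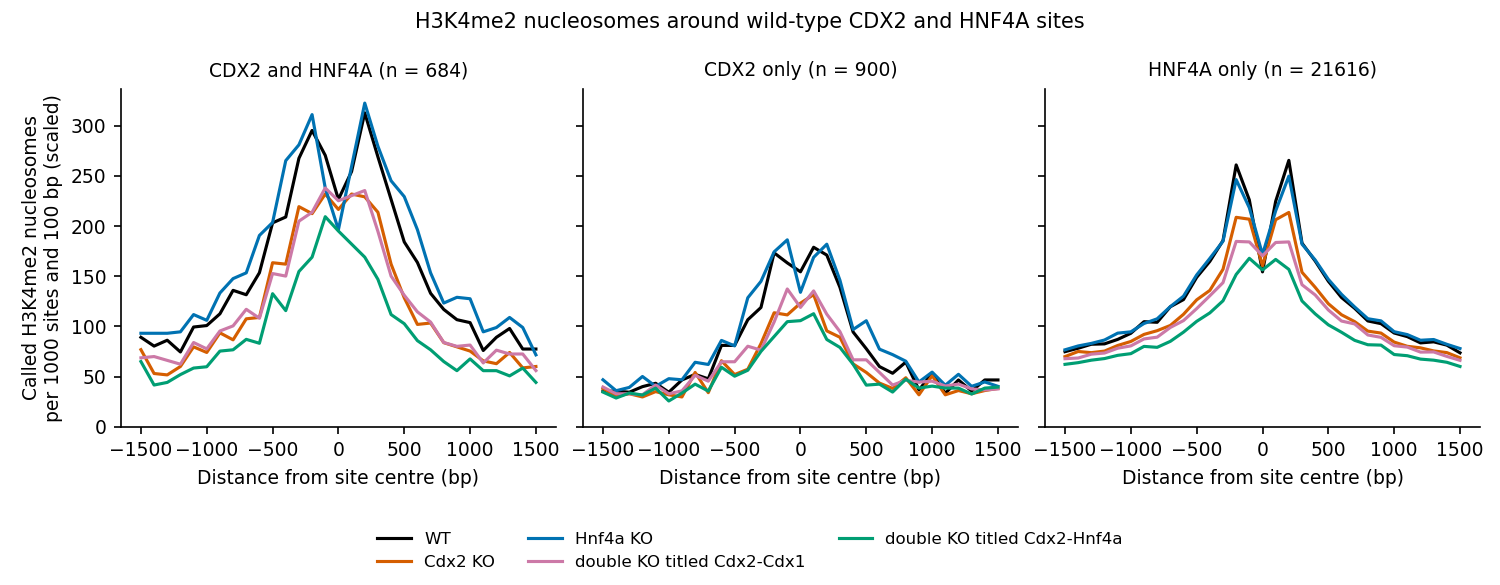
Called H3K4me2 nucleosomes per 1000 sites in steps of 100 bp (vertical axis, score of 52 or more, scaled to the wild-type list) by distance from the site centre in bp (horizontal axis), for 3 site classes and 5 libraries. Around co-occupied sites, and likewise around HNF4A only sites, the 3 lists without Cdx2 lay below wild type and Hnf4a knockout on both flanks.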

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

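All window scans in this part were chosen after the data were seen. H3K4me2 was counted in 5 kb windows across the genome, factor sites included. After an earlier scan of summed scores, 15 combinations of empty lists were tried at 5 minimum counts, with the lists as deposited and at a score of 52 or more.

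Some windows marked in wild type were empty in every list lacking Cdx2. With at least 3 nucleosomes in wild type and in Hnf4a knockout, 331 windows held none in Cdx2 knockout and none in either double knockout. The fullest lay on chromosome 11 at 118850001 to 118855000, with 20 nucleosomes in wild type and 21 in Hnf4a knockout, and held no CDX2 or HNF4A peak. The next lay on chromosome 1 at 130220001 to 130225000, with 19 and 16, and held a CDX2 peak in both wild-type libraries. Those listed after it, on chromosomes 4, 6 and 10, held no CDX2 or HNF4A peak. A CDX2 peak of either library lay in 32.3% (27.3 to 37.7) of the 331 windows, against 16.8% (16.4 to 17.2) of all 33424 wild-type windows. An HNF4A peak lay in 32.6% (27.6 to 38.0), against 32.0% (31.5 to 32.5), but this comparison turned with the minimum. It was 16.3% against 23.2% at a minimum of 1, 24.2% against 28.2% at 2, 39.5% against 34.9% at 4 and 47.5% against 37.3% at 5. For CDX2 the shares were 17.1% against 12.9% at 1, 26.7% against 15.1% at 2, 35.3% against 18.1% at 4 and 30.5% against 19.1% at 5. Windows empty only in the library titled Cdx2-Hnf4a, and so marked in Cdx2 knockout, held a CDX2 peak nearly as often. Their share was 29.5% (23.8 to 35.8) of 237 at a minimum of 3. It was 16.7% at 1, 23.3% at 2, 27.7% at 4 and 28.3% at 5. As deposited, the CDX2 share was thus not particular to windows empty in every list lacking Cdx2. At a score of 52 or more, 200 windows met the rule, with a CDX2 peak in 43.0% (36.0 to 50.2) and an HNF4A peak in 34.0%, against 16.8% and 32.2% of all wild-type windows. Of 202 windows empty only in the library titled Cdx2-Hnf4a at that score, 32.2% (25.8 to 39.1) held a CDX2 peak. In the opposite direction, 21 windows were marked in the 3 lists without Cdx2 and empty in wild type and Hnf4a knockout, and 167 were at a score of 52 or more. At that score the balance turned with the minimum. The first rule gave 2587 windows against 3801 in the opposite direction at 1, and 668 against 723 at 2. It gave 72 against 51 at 4 and 33 against 20 at 5. As deposited the first rule gave more at every minimum, with 4008 against 1024 at 1. The first rule needs nucleosomes in Hnf4a knockout and the opposite one needs none, so the looser threshold of that list favours the first. Counts as deposited thus cannot show which direction was commoner.

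In a different combination, 4 windows were marked in wild type, Cdx2 knockout and the library titled Cdx2-Hnf4a and empty in Hnf4a knockout and the library titled Cdx2-Cdx1. All 4, of which 2 were adjacent, lay on chromosome 2, which carries Hnf4a. With the double knockouts exchanged in the rule there were 0. The 2 counts were 146 and 65 at a minimum of 1, 17 and 0 at 2, 1 and 0 at 4, and 0 and 0 at 5. Those on chromosome 2 were 29 and 3 at a minimum of 1, or 19.9% (13.7 to 27.3) and 4.62% (0.962 to 12.9), and 6 and 0 at 2. Chromosome 2 held 7.61% of all wild-type windows at a minimum of 1. Of those empty only in Hnf4a knockout it held 11.5% (8.25 to 15.5). At a score of 52 or more the counts were 540 and 439, 54 and 23, and 8 and 2 at minima of 1, 2 and 3, of which 60 and 33, 8 and 0, and 4 and 0 lay on chromosome 2. The 60 and 33 were 11.1% (8.59 to 14.1) and 7.52% (5.23 to 10.4), against 7.60% of all wild-type windows. At that score and a minimum of 3, an HNF4A peak lay in 56.9% of 202 windows empty only in the library titled Cdx2-Hnf4a, 15.4% of 13 empty only in the library titled Cdx2-Cdx1 and 7.32% of 41 empty only in Hnf4a knockout. Tests of the place on chromosome 2 and of exchanged titles were made on the 4 windows that had prompted them and dropped, the latter also because 4 windows are too few for it. Which gene either library lacks stays open.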

How the results depend on the processing

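Of 67 alternative values, 37 moved by less than the 95% interval of the main value, 27 moved further and 3 called ratios went from below 1 to 1.00 or above. Among the values of the first 2 kinds, 7 lay on the other side of no difference from a main value whose own interval spans it. With only 1 library in most groups, unknown read depth sets what can be said of any single share. The cause of the moves listed here was not tested, except that stricter and equal-length lists hold fewer peaks and that leaving out a CDX2 library swaps shared sites for the peaks of 1 library.

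With centres within 200 bp, CDX2 replicate overlap was 19.6%, HNF4A kept 29.0% and co-occupancy 36.1%. With the upper 50% of every list, replicate overlap was 27.1%, CDX2 kept 42.8%, HNF4A kept 34.0%, co-occupancy 37.5% and the difference in HNF4A kept by CDX2 occupancy −3.21 points. With lists of equal length these were 18.7%, 47.0%, 53.7%, 27.1% and −6.91 points. The score-matched comparison of HNF4A kept by CDX2 occupancy was below every random set under all of its alternatives, but its gap shrank to −6.02 points without CDX2 wild-type replicate 2.

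Without CDX2 wild-type replicate 1 or 2, CDX2 kept was 8.60% to 11.6%, co-occupancy 11.8% to 26.4%, the difference in CDX2 kept by HNF4A occupancy 5.87 to 23.3 points, and H3K4me2 at CDX2 sites in Cdx2 knockout 0.799 to 0.801. HNF4A kept by CDX2 occupancy was 2.99 to 6.60 points, and the double knockouts relative to Cdx2 knockout were 0.962 to 0.996 and 0.786 to 0.803.

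H3K4me2 at HNF4A peaks in Hnf4a knockout was 0.682 with a 500 bp window, 0.811 with 2 kb and 0.960 in the upper 50% of each list. It was 1.45 without scaling, which multiplies sites and controls alike, and 1.01 (0.997 to 1.02) with lists of equal length. Of the settings chosen after seeing the data, a score of 52 or more gave 1.00 with an interval spanning 1 (0.991 to 1.01), and summed scores 0.984. It lay inside the control band except above it in the upper 50% of each list (percentile 98.3) and below it with summed scores (percentile 1.67). Relative to Cdx2 knockout, the library titled Cdx2-Cdx1 was at 1.12 without scaling and 1.10 in the upper 50% of each list, and the library titled Cdx2-Hnf4a at 0.829 without scaling. H3K4me2 at CDX2 sites in Cdx2 knockout stayed below every control set under all of its alternatives.

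Other settings for gene lists (sites within 5 or 50 kb) and motifs (50 bp) were not run, since no mm9 annotation or genome was used here. No paired analysis was possible because no test between groups was made.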

Other observations

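The tests of list length and of whether the H3K4me2 fall follows HNF4A, and the measure of nucleosome spacing, were chosen after the data were seen, the second with 0.701 and unmatched values of the rest already known, and the score-matched and count-matched tests before.

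At HNF4A peaks without CDX2, called nucleosomes dipped less at the centre in every knockout list than in wild type. The density of called nucleosomes within 100 bp of the centre, divided by that at 100 to 400 bp, was 0.764 (0.744 to 0.783) in wild type. It was 0.828 (0.807 to 0.849) in Hnf4a knockout, 0.943 (0.920 to 0.968) in Cdx2 knockout, 1.05 (1.02 to 1.08) in the library titled Cdx2-Cdx1 and 1.15 (1.12 to 1.18) in the library titled Cdx2-Hnf4a. At co-occupied sites the values were 0.846 (0.745 to 0.958) in wild type, 0.724 (0.635 to 0.823) in Hnf4a knockout and 1.00 (0.879 to 1.14) in Cdx2 knockout, with wild-type intervals overlapping both. The libraries titled Cdx2-Cdx1 and Cdx2-Hnf4a had 1.14 (1.01 to 1.29) and 1.24 (1.08 to 1.41). CDX2 sites without HNF4A had no clear dip in wild type, at 1.02 (0.887 to 1.17), and the interval overlapped those of Cdx2 knockout at 1.23 (1.04 to 1.44) and Hnf4a knockout at 0.947 (0.824 to 1.09). All lists were taken at a score of 52 or more, and each value comes from 1 library.

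The lower kept share of HNF4A at CDX2 sites in Cdx2 knockout was weighed against technical explanations. Weaker peaks falling under the calling threshold would put the share inside the band of score-matched sets, but its difference from their mean was −10.8 points, and it was below all of them. Without CDX2 wild-type library 2 the gap was smaller, at −6.02 points. In lists of equal length the gap was −12.1 points. Peaks with and without CDX2 were looked up in the same knockout list, so its length bears on both. That test therefore could not decide whether list length plays a part. Whether HNF4A binding rests on CDX2 at shared sites was not tested separately, and differences in peak shape or depth between these unreplicated libraries stay open.

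The fall of H3K4me2 at CDX2 sites in Cdx2 knockout was also weighed. A difference in how densely the lists were called would lower control sites as much, but count-matched HNF4A peaks without CDX2 averaged 0.873 against 0.746. A fall only through the loss of HNF4A would spare CDX2 sites with no HNF4A peak in wild type, where the ratio was 0.701, and would lower lost HNF4A peaks alike with and without CDX2. Lost peaks with CDX2 were at 0.694, below all sets of lost peaks without CDX2 matched on score and count (mean 0.810, band 0.777 to 0.843), while kept peaks with CDX2, at 0.906, lay inside their band (0.861 to 0.926), as that explanation needs. HNF4A or its loss under the calling threshold was not measured, and neither a direct part of CDX2 nor a shift in the makeup of the epithelium was tested.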
